A study of Mus musculus with 4 samples.

How the data were processed

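Acetylation of histone H4 at lysine 16 (H4K16ac) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells (ESC) and in neural progenitor cells (NPC) derived from them. Both came from 46c, an ES cell line that carries a GFP reporter in the Sox1 gene, which is switched on in neural progenitors. Per the labels, NPC were taken after 5 days of differentiation and sorted for GFP. Chromatin was digested with micrococcal nuclease (MNase), and the same Millipore antibody was used for both cell types. The 4 libraries were 1 H4K16ac library and 1 MNase input library per cell type.

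Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 0.12.7, SAMtools 0.1.7, bedtools 2.10.1 and SICER 1.1 were used on mouse genome build mm9. SICER joins neighbouring windows that hold more reads than the background into broad enriched regions, called islands. The names of the deposited lists give a window of 200 bp, a gap of 600 bp and a false discovery rate of 0.01. Each list gives the chromosome, start and end of an island and a whole number, which was read as the count of H4K16ac reads in the island, as deposited by the authors without scaling to depth or to input. Neither the removal of duplicate reads nor the way in which the input entered the island calls is given in the sources used here. The input libraries entered the values only through those calls.

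Starts and widths were multiples of the window in 100% of islands of both lists once the end was read as the last base, and coordinates were moved by 1 to count from 1. The lists hold only reads inside islands, so the total depth of each library is unknown. The island reads came to 17935144 in ESC and 24386370 in NPC. The median island held 277 reads in ESC and 313 in NPC, for which counting error alone is 6.01% and 5.65%. Sequenced reads without molecular identifiers are not independent molecules, so intervals of read shares cover counting error only. Intervals of shares, medians or totals over islands or regions treat these as independent draws and do not give their spread. Neighbouring islands may not be independent, and no interval covers variation between cultures.

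Overlap was counted from 1 shared base upward and set beside 1000 seeded circular shifts of the other list within each chromosome. Islands of both lists were merged into regions. In regions called in both lists, reads per 1000000 island reads (RPM) were compared as log2 NPC over ESC, with an exact Clopper-Pearson 95% interval of the share of reads. Intervals of medians came from order statistics, and those of covered or shared bases from 1000 bootstrap draws over islands. A region called in 1 list only was given no ratio, because the lists hold no reads outside islands. Ratios of shared regions also leave out reads outside called islands. The 1 ESC island on the mitochondrial chromosome was kept out of overlaps, counts of broad islands and region ratios, and was counted in the totals, densities and chromosome shares of its list. Reads per kb of island are called density.

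With 1 library per cell type there was no replicate check of any difference between ESC and NPC, no library could be left out in turn, and no p-value was computed. The comparisons, their alternatives and the rule for naming regions were fixed before the data were examined. The rule named the 5 regions with most RPM in each cell type alone, and the 5 highest and 5 lowest log2 values among shared regions with at least 100 reads. It also named the 5 widest islands and the 5 with most reads in each list. Alternatives covered the overlap required, stricter read and width minimums, equal list lengths, merging across gaps of up to 2000 bp, and the scaling of the ratios. Dense narrow islands (at most 2000 bp and at least 120 reads per kb), broad islands (at least 8000 bp) and fixed moves of a list by 100 to 500 kb were defined after seeing the data. So were the settings without X and Y, without very dense islands, and with density not scaled to island reads. Results by gene (promoter islands, genomic distribution and gene lists) were not run, because no gene annotation of mm9 was used here. Regions are therefore given by position alone.

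The overlap code was tested on a simulated list made from ESC islands of chromosomes 1 to 19 and X. The ratio code was tested on read counts simulated for the regions called in both lists. All 16221 islands given a counterpart were found, with 0 false overlaps. In the real lists, counts of overlapped islands and merged regions equalled those of bedtools 2.31.1. In 14478 simulated regions, 95.4% of intervals held the simulated ratio. Unchanged regions had the same expected reads in both libraries, so unlike called widths were not simulated. The 100 regions changed 2-fold had a median log2 of 1.01 and the 100 changed 4-fold a median of 2.01. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.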

Results

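H4K16ac islands were compared between undifferentiated 46c ES cells and sorted day 5 neural progenitors, 1 ChIP library each, to describe where the mark lies before and after neural differentiation. The ESC list held 40570 islands with 17935144 reads, and the NPC list held 48278 islands with 24386370 reads. Differences between the cell types had no replicate check. Intervals of read shares cover counting error only. Those over islands or regions treat islands or regions as independent draws and do not give their spread. All positions are on mm9.

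NPC had more and wider H4K16ac islands than ESC, whereas the median ESC island was denser in reads. NPC islands numbered 1.19 times those of ESC (95% interval 1.17 to 1.21) and covered 307 Mb against 192 Mb. The median island was 4200 bp wide in NPC and 3000 bp in ESC. Broad islands of at least 8000 bp on nuclear chromosomes numbered 11658 in NPC and 5975 in ESC. At the other end of the range, islands of at most 2000 bp with at least 120 reads per kb numbered 7523 in ESC and 628 in NPC.

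Median density was 93.3 reads per kb in ESC islands and 76.6 reads per kb in NPC islands. Per 1000000 island reads, these medians were 5.20 and 3.14 reads per kb. The ESC list also had the wider spread of densities, with an SD across islands of 36.7 reads per kb, against 15.2 reads per kb in NPC. Islands with at least 120 reads per kb made up 28.4% of the ESC list and 1.57% of the NPC list. Numbers and widths of called islands also depend on library depth and on background, neither of which was used here.

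**Figure D1:**
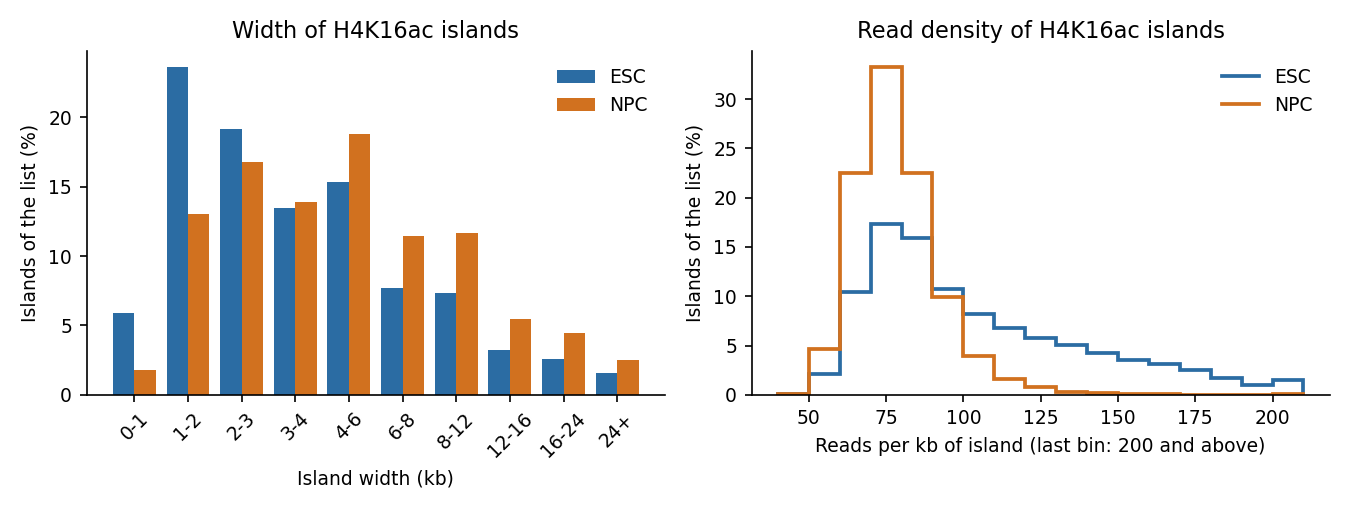
Share of islands of each list (%) by width in kb (left, bars) and by reads per kb (right, steps, the last bin holding all islands of 200 reads per kb or more), ESC in blue and NPC in orange, 1 library each. Median width is 3000 bp in ESC and 4200 bp in NPC, and median density is 93.3 and 76.6 reads per kb.

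Most islands of either cell type had no called counterpart in the other. The lists hold no reads outside islands, so a stretch without a called island may still carry the mark. Of 40569 ESC islands on nuclear chromosomes, 16157 (39.8%, exact interval 39.3% to 40.3%) overlapped an NPC island. Of 48278 NPC islands, 16734 (34.7%, 34.2% to 35.1%) overlapped an ESC island. The 98986000 bp common to both lists made up 51.6% of ESC island bases and 32.3% of NPC island bases. Merging gave 70434 regions, of which 14478 were called in both cell types, 24412 in ESC only and 31544 in NPC only.

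Circular shifts gave a mean overlap of 18.9% for ESC islands and 16.1% for NPC islands, and none of the 1000 shifts reached the observed share in either list. The observed overlap was 2.11 times the shifted one in ESC and 2.16 times in NPC. Moving a list by only 100 to 500 kb, a setting chosen after seeing the data, gave 30.3% and 25.9%, which lowered these ratios to 1.32 and 1.34.

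Most broad ESC islands overlapped an NPC island, and few dense narrow ones did. The share overlapped by NPC islands rose from 6.50% in the narrowest decile of ESC islands to 89.6% in the widest. Among broad ESC islands, 85.0% (84.1% to 85.9%) were overlapped, against 30.1% under circular shifts and 60.1% after moves of 100 to 500 kb. Broad NPC islands were overlapped less often, at 48.3% (47.4% to 49.2%), near the 44.0% found after the moves. Among the 7523 dense narrow ESC islands, 699 (9.29%, 8.64% to 9.97%) were overlapped, against 13.2% under circular shifts and 11.3% after the moves. Dense narrow NPC islands differed from these, since 341 of 628 (54.3%, 50.3% to 58.2%) overlapped an ESC island, against 8.93% under circular shifts. By density, the overlap of ESC islands was highest in decile 3 from the bottom, at 60.0% against 39.3% after the moves. In the densest decile it was 21.9% against 15.1%. Median widths in those deciles were 4400 and 1400 bp, so the fall with density cannot be told apart from width. These width and density classes were set after seeing the data.

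**Figure D2:**
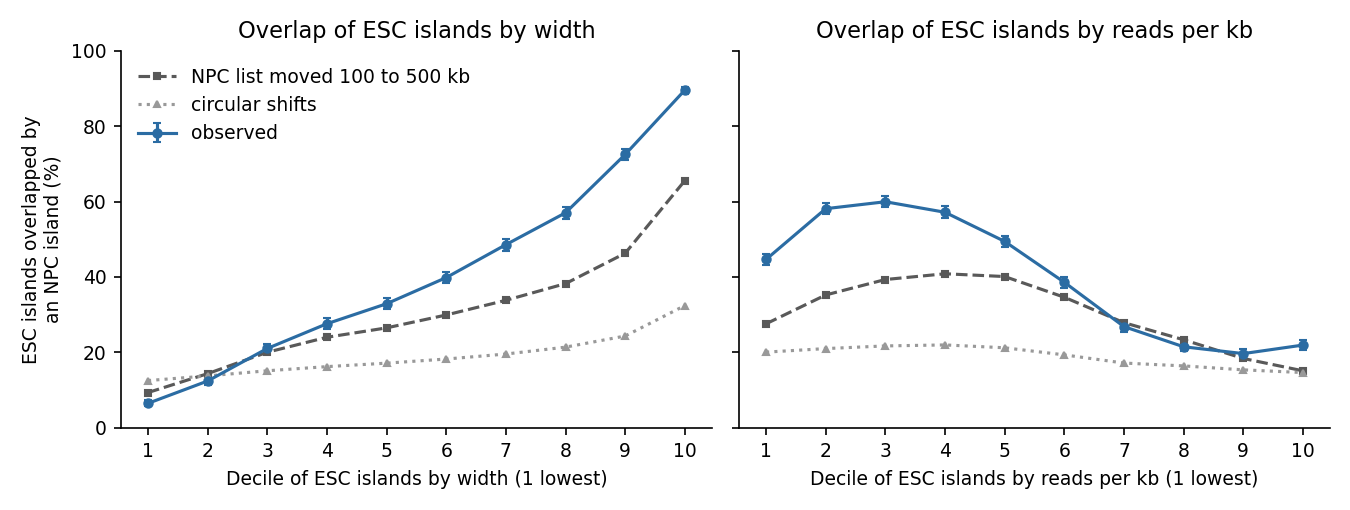
Share of ESC islands overlapped by an NPC island (%) in deciles of ESC islands by width (left) and by reads per kb (right). Points are observed shares with exact 95% intervals, dashed lines the mean after moving the NPC list by 100 to 500 kb, and dotted lines the mean of 1000 circular shifts. Observed shares rise from 6.50% to 89.6% with width.

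In regions called in both cell types, NPC held a smaller part of its island reads than ESC. The median log2 NPC over ESC was -0.49 (-0.51 to -0.48), with an SD across the 14478 regions of 1.07, and 22.1% of regions had a value above 0. Shared regions held 60.9% of ESC island reads and 45.8% of NPC island reads, over a median called width of 5400 bp in ESC and 5800 bp in NPC. By density, scaled to the island reads of each list, the median was -0.51 with an SD of 0.40, and 1.65% of regions lay above 0. Without scaling to island reads, a setting chosen after seeing the data, the density median was -0.07 with 39.3% of regions above 0. The direction of single regions depended on the scaling. Scaling by reads in shared regions moved every log2 value up by 0.41, to a median of -0.08 with 43.7% of regions above 0. Scaling by the median ratio moved them up by 0.49, with 50% of regions above 0 by construction.

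The shared regions with the highest log2 values were those in which a short ESC island met a long NPC one. The lists hold no reads outside islands, so ESC reads in the uncalled part of such a region are missing from its ratio and interval. On chromosome 3, positions 87528201 to 87561000 held 112 ESC reads in 1 kb of called island and 3083 NPC reads in 32.2 kb, a log2 of 4.34 (4.07 to 4.62). On chromosome 13, positions 48828201 to 48868800 had 131 and 3361 reads over 1.4 and 40.6 kb, a log2 of 4.24 (3.99 to 4.50). The other 3 named regions began at 134624001 and 47018601 on chromosome 4 and at 85083401 on chromosome 10, with values of 4.10, 3.91 and 4.05.

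The lowest values were the mirror image, with a long ESC island and a short NPC one. NPC reads in the uncalled part of these regions were missing in the same way. On chromosome 11, positions 51446401 to 51466400 held 2465 ESC reads in 20 kb and 104 NPC reads in 1.2 kb, a log2 of -5.01 (-5.31 to -4.73). Also on chromosome 11, positions 77989401 to 77999800 held 2050 reads in 10.4 kb and 91 reads in 0.6 kb, a log2 of -4.94 (-5.26 to -4.63). The other 3 began at 45699801 on chromosome 17, 146602801 on chromosome 4 and 114529801 on chromosome 11, with values of -4.92, -4.91 and -4.76. The called width carried most of the difference in the 5 lowest regions. In the 5 highest it carried all of it, since their log2 by density, scaled to island reads, was below 0. By density, the 5 highest regions lay between -0.86 and -0.03, and the 5 lowest between -0.95 and -0.39.

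The region called in NPC only with the most reads was also the widest island of either list. It spanned 152.4 kb of chromosome 6, positions 114436801 to 114589200, with 23801 reads (976 reads per 1000000 island reads, RPM) at 156 reads per kb. The 50 other NPC islands within 500 kb had a median of 85.6 and a maximum of 127 reads per kb, so that the island was 1.83 times as dense as that median. Whether this segment is present in extra copies in these cells was not tested, since input reads were not used here. No ESC island was called from 113691801 to 114592600, a stretch of 900.8 kb in which 28 NPC islands covered 54.4% of the bases. The next NPC-only regions were at 27491601 to 27565000 on chromosome 17 (361 RPM), 18130401 to 18202800 on chromosome 16 (315 RPM), and 139815401 to 139887400 and 105196601 to 105261800 on chromosome 7 (266 and 247 RPM). Their densities were 90.3 to 120 reads per kb.

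**Figure D3:**
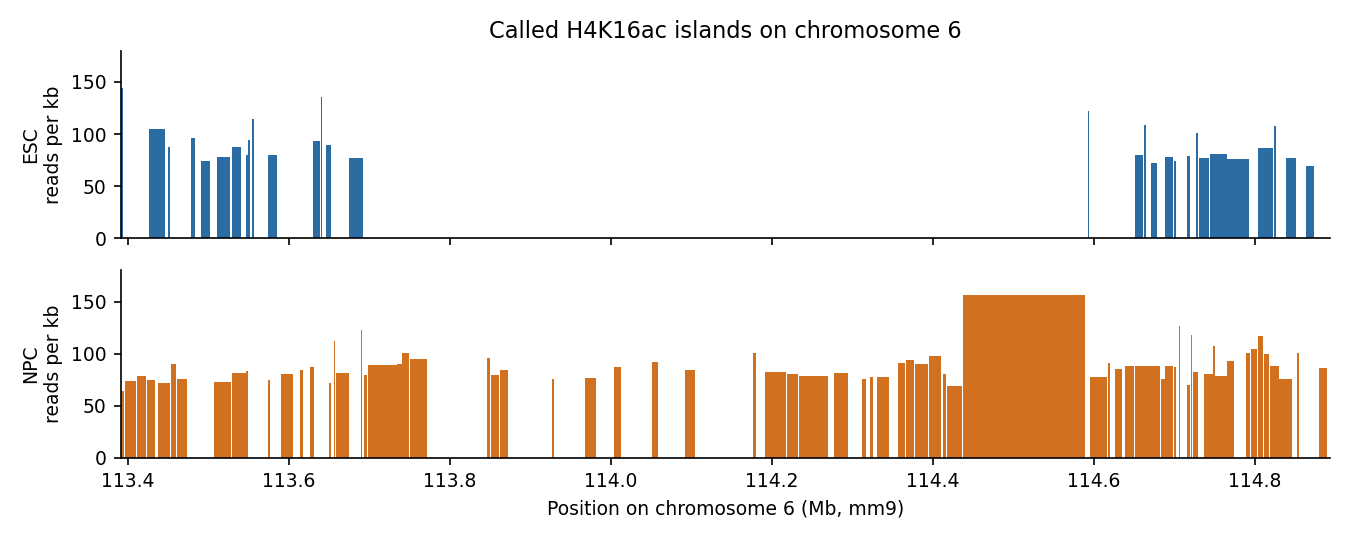
Islands called in ESC (top, blue) and NPC (bottom, orange) around the widest NPC island on chromosome 6, position in Mb on the x axis and reads per kb of each island as bar height, 1 library each. The NPC island of 152.4 kb stands at 156 reads per kb, and no ESC island was called over 900.8 kb.

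The regions called in ESC only with the most reads were denser. On chromosome 9, positions 2999801 to 3077200 held 36409 reads (2031 RPM) at 470 reads per kb. On chromosome Y, positions 2847601 to 2902600 held 16514 reads (921 RPM) at 300.3 reads per kb. The others were 85227601 to 85296800 on chromosome 1 (707 RPM), 67002201 to 67050400 on chromosome 7 (387 RPM) and 47600601 to 47637000 on chromosome 6 (370.0 RPM), at 144 to 183 reads per kb. Whether reads at the densest positions came from sequence with several genomic copies was not tested.

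Most of the widest domains overlapped an island of the other cell type, as wide islands also did after moves of 100 to 500 kb. Of the 100 widest islands, 96% in ESC (90.1% to 98.9%) and 86% in NPC (77.6% to 92.1%) overlapped an island of the other list, against 86.5% and 82% after the moves. Ranked by reads per kb instead, the shares were 51% and 75%, against 22.1% and 18.6%. The widest ESC island, 124.4 kb at 19914001 to 20038400 on chromosome 8, had 96.0% of its bases in NPC islands. The next were 105.6 kb from 28108001 on chromosome 17, 101.8 kb from 138951201 on chromosome 4, 98.2 kb from 103804001 on chromosome 12 and 94.2 kb from 118503801 on chromosome 5, each with at least 93.9% of its bases shared. After the chromosome 6 island, the widest in NPC was 123 kb at 32990401 to 33113400 on chromosome 2, with 98.5% shared. The others were 114.6 kb from 120927601 on chromosome 6 and 106 kb from 140529801 on chromosome 5, with 94.2% and 91.7% shared, and 99.6 kb from 30820001 on chromosome 17, with 21.5% shared.

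By reads, the leading NPC island lay on chromosome 11, positions 3025201 to 3100000, with 30988 reads. It fell inside an ESC island at 3022201 to 3100200 with 34510 reads, which was second in ESC after the chromosome 9 island. The widest ESC island, on chromosome 8, came next with 32807 reads, and its NPC counterpart at 19914001 to 20009000 had 23556. Another chromosome 8 island, from 19679601, had 15115 ESC and 13458 NPC reads. The densest island was the same in both lists, at 98502201 to 98507600 on chromosome 2, with 717 reads per kb in ESC and 594 in NPC. This last island was named after its values were seen. For these shared islands too, a source of reads in sequence with several genomic copies was not tested.

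Islands covered more of every autosome in NPC than in ESC, and less of the X chromosome. The ratio of covered bases, NPC over ESC, ranged from 1.22 on chromosome 19 to 1.84 on chromosome 7. Chromosome 11 was the most covered autosome in both, at 12.1% in ESC and 19.9% in NPC, and chromosome 3 the least covered autosome, at 4.08% and 6.03%. On X, islands numbered 1046 in ESC and 107 in NPC, and covered bases were 2053 kb and 493 kb. These made up 1.23% and 0.296% of its length up to the last island, so X was already covered less than any autosome in ESC. X held 1.54% of ESC and 0.192% of NPC island reads, a ratio of the shares of 0.125 (0.124 to 0.126), whereas the autosomes ranged from 0.775 to 1.13. Leaving out dense narrow islands, a setting chosen after seeing the data, gave 0.189. On Y, 15 islands were called in ESC and 1 in NPC.

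X islands in ESC were narrow and dense, with a median of 1400 bp and 139 reads per kb. The 107 NPC islands on X had medians of 3000 bp and 69.2 reads per kb. Of the ESC islands on X, 44 (4.21%, 3.07% to 5.61%) overlapped an NPC island, against 40.8% of autosomal ESC islands. Because X held few NPC islands, its share was low after moves of 100 to 500 kb too, at 0.848%. In the 44 shared regions on X the median log2 was -1.67 (-1.92 to -1.05), and by density -1.03. Autosomal regions had medians of -0.49 and -0.51. The density value on X was at the 16.2 percentile of 10000 lists of autosomal shared regions matched on ESC density and width. The median of those lists was -0.92, so the X value did not stand apart from them. Both sets hold only regions that passed the NPC call. The comparison therefore cannot tell how density changed in ESC islands on X without an NPC counterpart.

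**Figure D4:**
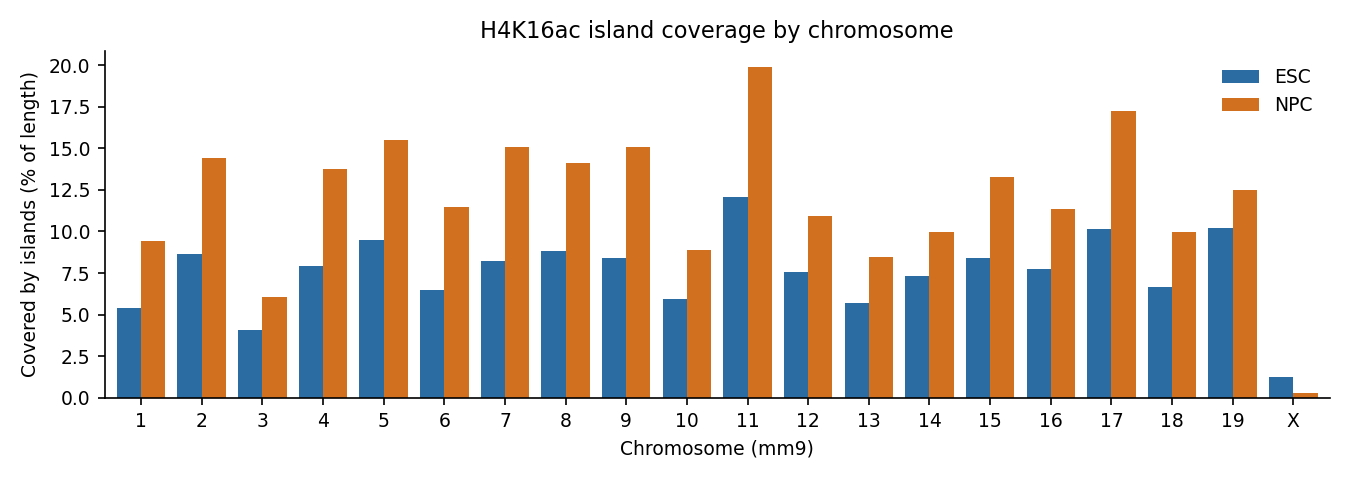
Share of each chromosome covered by islands (% of the length up to the last island), ESC in blue and NPC in orange, 1 library each. Bars are higher in NPC on each autosome, up to 19.9% on chromosome 11, and lower in NPC on X.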

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

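The ESC list held 1 island on the mitochondrial chromosome, which was left out of overlaps, counts of broad islands and region ratios but counted in the totals of its list. It spanned positions 1 to 16200 and held 4431 reads, or 274 reads per kb, denser than 99.9% of nuclear ESC islands. The NPC list held 0 islands there. Mitochondrial DNA carries no histones, so this is a signal outside the mark that was measured. No cause was tested, and with 1 library per cell type no check for outlying samples was possible.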

How the results depend on the processing

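Of 69 values recomputed under other settings, 24 stayed within the interval of the reported value and 45 left it. Of the 24, 2 came from the minimum of 100 reads, which removed no shared region, and 1 was the ratio of island numbers under the median read minimum, which keeps about the same part of each list. Of the 45, 1 was the share above 0 under scaling by the median ratio, which is fixed by construction. Settings without dense narrow islands, without very dense islands, without X and Y, with density not scaled to island reads, or with a list moved by 100 to 500 kb were chosen after seeing the data. The intervals do not cover variation between cultures, and the cause of each shift was not tested. Equal list lengths fix the ratio of island numbers at 1, and scaling by the median ratio fixes the median log2 at 0, so neither gave a value. The alternatives for promoter islands by gene, genomic distribution and gene lists were not run. The unknown library depth limits the reading of islands called in 1 list only.

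The ratio of island numbers was 1.24 for islands of at least 1000 bp and 1.44 without dense narrow islands, and that of covered bases 1.54 with equal list lengths and 1.67 without dense narrow islands. The share of ESC islands overlapped was 33.6% when 50% of the length was required, 42.7% with the median read minimum, 41.3% from 1000 bp, 35.2% with equal lengths, 37.9% with gaps of 2000 bp merged, 40.8% without X and Y and 46.1% without dense narrow islands. For NPC islands it was 29.0% when 50% of the length was required, 36.0% with the read minimum, 35.8% with equal lengths, 36.1% with gaps merged and 33.3% without dense narrow islands. Shared bases of ESC were 52.6% with the read minimum, 50.04% with equal lengths, 52.4% with gaps merged and 53.5% without dense narrow islands, and those of NPC 32.9% with the read minimum.

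The overlap relative to shifted lists, in ESC and NPC in turn, was 2.72 and 2.77 with the read minimum, 2.15 and 2.20 from 1000 bp, 2.004 and 2.08 with equal lengths, 1.95 and 2.003 with gaps merged, and 2.30 and 2.33 without dense narrow islands. It was lowest, at 1.32 and 1.34, against lists moved by 100 to 500 kb. The median log2 in shared regions was -0.082 when scaled by shared-region reads, -0.51 by reads per kb and -0.068 by reads per kb not scaled to island reads. The share of regions above 0 was 43.7%, 1.65% and 39.3% under these settings and 50% under the median ratio. The ratio of X read shares was 0.150 by bases, 0.159 with the read minimum and 0.189 without dense narrow islands. Ranked by reads per kb, 51% of the top 100 ESC islands and 75% of the top 100 NPC islands were overlapped.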

Other observations

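All windows and tests in this part were chosen after seeing the data. At the scale of 1 Mb the landscapes of the cell types were alike. Across 2411 autosomal windows with an island, which are not independent replicates, the bases covered in ESC and NPC had a Spearman rho of 0.885. The autosomal window of 500 kb with the largest gain in covered share, at 114200001 to 114700000 on chromosome 6, went from 6.4% in ESC to 84.4% in NPC. It holds the NPC island of 152.4 kb named in the report, for which extra copies of the segment were not tested. The next were at 130800001 to 131300000 on chromosome 4 (4.48% and 78.2%), 151100001 to 151600000 on chromosome 7 (7.84% and 78.2%), 119500001 to 120000000 on chromosome 4 (0.4% and 69.1%) and 113200001 to 113700000 on chromosome 12 (8.48% and 75.4%).

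Over all 24633 autosomal windows of 500 kb, which overlap, the median difference was 0.28 percentage points. Coverage was higher in NPC in 54.2% of them and higher in ESC in 40.2%. The largest losses were smaller than the largest gains. The window with the largest loss, at 14900001 to 15400000 on chromosome 5, had 34.2% covered in ESC and 1.8% in NPC. Of the 5 windows with the largest losses, 3 lay near one end of chromosome 14. They were at 4000001 to 4500000 (52.5% and 26.4%), 6500001 to 7000000 (38.9% and 13.0%) and 7700001 to 8200000 (52.7% and 28.6%). The remaining window, at 84800001 to 85300000 on chromosome 1 (24.4% and 2.04%), takes in the ESC-only region named in the report. Whether sequence with several genomic copies, or a difference in copies, plays a part in these losses was not tested.

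The 7523 dense narrow ESC islands, of which 9.29% had an NPC counterpart, raise the question whether a short form of the mark was lost or escaped the NPC calls. Fewer NPC reads with no other difference would have to lower density to 0.511 of the ESC value for the lower quartile of these islands to reach the 5th percentile of narrow NPC islands. At that ratio 11.3% of broad ESC islands would stay above the 1st percentile density of the NPC list, but 72.8% (71.7% to 73.9%) of them had at least 50% of their length in NPC islands, against 33.1% after moves of 100 to 500 kb, which argues against fewer reads alone. Lower enrichment over background in NPC stays open: the slope of log2 NPC on log2 ESC density was 0.313 (0.268 to 0.357), but the reverse slope of 0.518 was also below 1, so scatter in either library could give it. Interspersed multi-copy sequence stays open as a source, since no repeat annotation was used here. The dense narrow ESC islands numbered 3.68 per Mb on X (3.39 to 3.98) against 2.79 on autosomes, whereas broad ones numbered 0.138 and 2.41. Any source not tied to broad islands could give such counts, multi-copy or not, so they cannot decide this. A difference between the cell types stays untested.

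The low number of NPC islands on X was weighed in the same way, and no explanation was excluded. X islands in ESC may be of a kind seldom found in NPC: autosomal ESC islands matched on width and density were overlapped at 17.6%, but 17.2% followed from NPC coverage nearby, as lists moved by 100 to 500 kb showed. The matched autosomal islands thus had hardly more NPC counterparts than nearby coverage gave, whereas X islands were overlapped at 4.21% against 0.848% after the moves. All these shares follow the number of NPC islands nearby, so they cannot tell why NPC islands were few on X. A single X copy may matter more in a list near its lower density limit, and halving the density of NPC autosomal islands gave 104 X islands against 107 called with the 1st percentile as the limit, but 996 with the lowest density and 50.3 with the 5th percentile. With the 1st percentile as the limit, the halved NPC islands had a median density of 59.4 reads per kb, against 69.2 in the X islands called. In ESC the same model gave 824 X islands against 1046 called, but a median density of 71.3 reads per kb against 139. A change of the X chromosome with differentiation stays open and untested.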
